A study of Mus musculus with 2 samples.

How the data were processed

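H3K27me3 was measured by chromatin immunoprecipitation with a Millipore antibody and SOLiD 3 Plus fragment sequencing, per the labels' protocols, in 1 wild-type and 1 Jmjd3-/- library of bone marrow macrophages. The authors deposited 1 list of aligned tags per library and chromosome, each line giving the start, end and strand of 1 tag of 50 bases, with repeated positions kept. The build was mm9 per the submitters' processing notes, and all tags ended within the mm9 chromosome lengths. The aligner is not given in the sources used here. Of its settings, the names of the deposited lists give a mapping of 50 bases with mismatches allowed. The score column of the deposited lists held the constant 900 and was not used. Groups followed the genotype label. The source label of the knockout library reads wild type, and that conflict was left unresolved.

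Tags at the same position and strand were counted once, since they can be PCR copies, and each tag was moved 100 bases towards the fragment centre. Autosomes were divided into windows of 5 kb. A window was enriched when the mean of both libraries' tag shares was at least 3 times the median of windows with tags, and enriched windows with a gap of at most 1 window were joined into domains. The deposited tags were summed to counts per domain and locus. The ratio of knockout to wild-type counts, scaled by autosomal distinct tags, was given with its exact 95% conditional binomial (Clopper-Pearson) interval. A domain or locus was called higher or lower when the ratio was at least 1.5-fold and the interval excluded 1. Shares carry Wilson intervals, and the interval of a median over domains is the binomial interval of its rank. No p-value was computed, because there is 1 library per genotype. Distinct tags are not certain to be independent molecules, so intervals and limits cover counting error only. The pooled tags were also dealt at random into pseudo-libraries of the same sizes 20 times, with domains called again each time. Window grades in which level and ratio come from opposite strands were added after the data were examined.

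No gene annotation of mm9 was used here. The planned counts at promoters and over whole gene lists were therefore not run. In their place, tags were counted at 57 loci with mm9 positions from general knowledge, of which 13 were fixed before the data were examined. The other 44 were drawn from the gene lists after the domains and the 13 had been seen but before their own counts were taken, with 5 kb added on each side, except that Pax2 had already been seen as the widest domain. The lists for dendritic, erythroid, neutrophil, osteoclast and stromal cells were not counted, and some list members are not reported here. Chromosome and order were checked against a RefSeq gene table of GRCm38, of which no coordinate is used. All 53 loci found in it lay on the same chromosome, and 35 of 35 neighbouring pairs were in the same order. The rule for naming loci and domains, fixed before the data were examined, took the targeted gene, every locus of the fixed set, the 12 domains with the largest rise and the 12 with the largest fall by the interval bound nearest to 1, and the 10 densest domains. The text gives a selection of these in full. A group's pooled ratio was set among 10000 random sets of segments of the same length and within 20% of the same level. At Kdm6b, tags of the locus and 100 kb on each side were dealt at random to both libraries in 10000 draws, a test chosen after seeing the data.

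The calling rule was tested on simulated counts for the 9815 domains already chosen, with 200 changed. It called 32.4% of the 71 domains changed 1.5-fold, 81.5% of the 54 changed 2-fold and 81.3% of the 75 changed 3-fold, and 2.69% of the 9615 unchanged ones. The changed domains had medians of 43, 86.5 and 42 tags in that order, so these rates do not compare fold changes at equal counts. The intervals covered the simulated ratio in 96.6% of all simulated domains that had a ratio, changed and unchanged. Depth limits the loci, since the median 5-kb window holds 6 wild-type and 3 knockout tags.

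Alternatives kept all tags, left out the shift, used 1 strand, scaled by background windows of 10 kb or by domains, set the threshold to 2 or 5 times the median, used windows of 2 or 10 kb, thinned the wild-type library, called domains in 1 library, applied a 2-fold rule, or left out the chromosome above 1.25 times the median density. Choosing and measuring on opposite strands, keeping domains of at least 20 kb, leaving out windows with tags stacked over 2 times the mean and counting the added loci without the added 5 kb were chosen after seeing the data. Tags on chromosomes X, Y and M were counted and stay outside the autosomal comparisons. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.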

Results

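H3K27me3, the trimethylated form of lysine 27 of histone H3 that Polycomb complexes deposit at silent genes, was mapped by chromatin immunoprecipitation and SOLiD sequencing in mouse macrophages. The cells were grown from bone marrow of mixed 129 X B6 mice, in medium with M-CSF at 20 ng/ml over 5 days. There was 1 library of wild-type cells and 1 of Jmjd3-/- cells. Jmjd3, encoded by Kdm6b, is a demethylase that removes this mark. The title and genotype labels of the second library name the knockout, while its source label names wild type, and the genotype label was followed. The wild-type library held 9747746 aligned tags of 50 bases at 3307803 distinct positions, which is 33.9% of its tags. The knockout library held 8809092 tags at 2051276 distinct positions, or 23.3%. Each distinct position was therefore read 2.95 times on average in wild type and 4.29 times in the knockout. On the autosomes, 3227443 and 2005519 distinct tags remained, which is 1.31 and 0.811 per kb. With 1 library per genotype no difference has a replicate check, so every ratio compares these libraries, not the conditions, and each interval covers counting error only.

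The targeted gene was examined before any other locus. Kdm6b, on chromosome 11, carried little H3K27me3 in either library, at 1.14 times the median density in wild type and 0.437 times in the knockout. The 17-kb locus held 21 wild-type and 5 knockout tags. Its log2 knockout over wild-type ratio was -1.38, with an interval from -3.15 to 0.06 that included 0. A stretch that crossed its edge and lay partly outside the counted locus, from 69203761 to 69216419 of mm9, held 15 wild-type tags and no knockout tag. There 9.32 knockout tags would match the wild-type density, and a count of 0 allows up to 3. When the pooled tags around the gene were dealt to both libraries at random, 1.18% of 10000 draws left as full a stretch over the locus. Of 136458 overlapping autosomal segments with the length and level of the locus, 3.34% lay on such a stretch in the libraries as sequenced. Over all autosomes, 2203 stretches without a knockout tag were as full, against 1417 on average in 20 random splits. The missing tags go the way of the knockout label, but the stretch has edges set by these tags themselves, and the deleted part of the gene is not given in the sources used here. When the scale was set to the median of all marked domains, the ratio at Kdm6b was -1.73 and passed the size and interval rule as lower. With background scaling it was -1.25 (-3.01 to 0.20) and did not pass. Domain scaling lowers every ratio, and under it 28 of the 37 unmarked loci were below 0. Of the 37, 8 were then called lower and 0 higher, so that call does not single out Kdm6b.

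**Figure D1:**
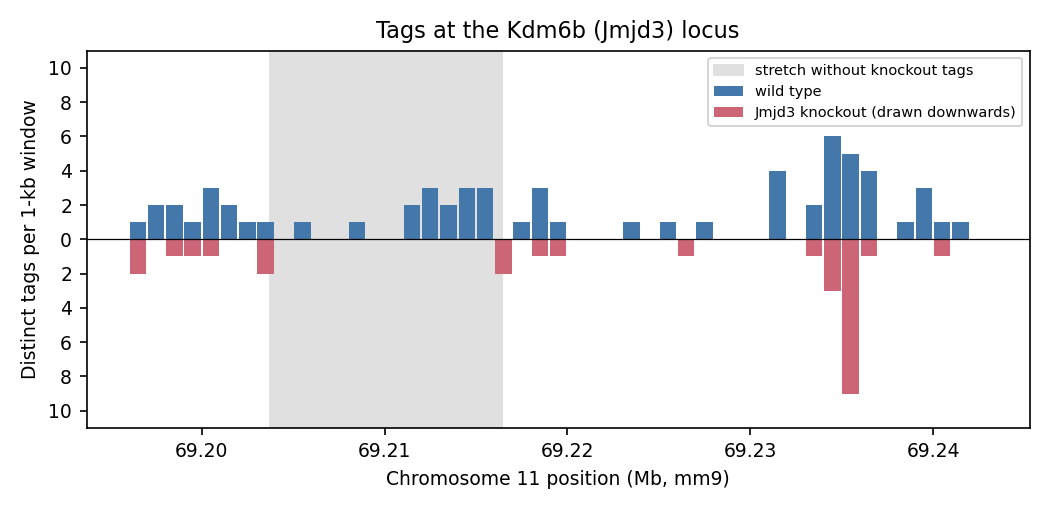
Distinct tags in 1-kb windows (vertical axis, number of tags) along chromosome 11 (horizontal axis, Mb of mm9) around Kdm6b, with wild type drawn upwards and the knockout downwards, 1 library each. The grey stretch holds 15 wild-type tags and no knockout tag, and counts per window stay low in both libraries.

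The next question was where the mark lay in these macrophages. Among the broadest marked regions were known Polycomb targets, genes for developmental transcription factors. The widest domain, 260 kb on chromosome 19 from 44655001 to 44915000, covered Pax2, a regulator of kidney development. The Hoxc cluster lay in a domain of 245 kb, the Hoxb cluster in 205 kb, the Hoxa cluster in 200 kb and the Hoxd cluster in 165 kb, ranking 2, 5, 9 and 23 by width. Lhx2, a regulator of forebrain development, lay in a domain of 120 kb and Gata4, a cardiac regulator, in one of 95 kb. In all, 24629 of 494476 windows of 5 kb were enriched and formed 9815 domains covering 134.685 Mb, or 5.45% of the autosomes. Most were narrow, with 5187 of a single window, and 2022 spanned at least 20 kb. Called alone, the wild-type library gave 17281 enriched windows and the knockout library 49614, of which 15100 were shared, against 1734 for independent sets. These numbers do not rest on a common threshold, since each library's own median window, with 6 and 3 tags, set it at 18 and 9 tags, and the knockout threshold was the lower after scaling to library totals. With the wild-type library thinned to the knockout depth, it gave 16910 enriched windows, of which 83.7% were shared. The shared windows were 28.5% of the knockout windows, and each threshold still came from the library's own median.

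The comparison the design implies is whether cells without this demethylase carry more of the mark. Marked regions as a class held more of the tags in the knockout library. Domains took 23.5% of its autosomal tags (95% Wilson interval 23.42 to 23.54) against 18.5% in wild type (18.45 to 18.54), a ratio of 1.27. The median log2 ratio of the 9815 domains was 0.35 (interval of the median 0.34 to 0.36), or 1.28-fold, and 8022 domains were above 0. By the rule of at least 1.5-fold with an interval excluding 1, 1092 domains were higher and 14 lower in the knockout library. Random splits of the pooled tags gave a median of 0.06, with 227 domains higher and 80.5 lower on average over 20 draws. Among the domains of at least 20 kb, 1901 of 2022 were above 0, with a median of 0.34. Scaling to the median ratio of background windows lowered the log2 scale of the knockout by 0.13 and gave 2003 domains higher and 3 lower. Scaling to the median domain, a shift of 0.35, gave 161 higher and 161 lower, a balance that this centring fixes by construction. Domains called in the wild-type library alone had a median of 0.082, with 376 higher and 187 lower, and those called in the knockout library alone one of 0.57, with 3328 higher and 2 lower.

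The ratio followed the level of the mark. Windows were graded by their tags on 1 strand and measured on the other, so that counting error could not link the level and the ratio. In the emptiest class, below 0.5 times the median, the log2 ratio was -0.26 (-0.27 to -0.25) with the level taken on the plus strand and -0.25 with the level on the minus strand. It was 0.28 in both directions at 3 to 5 times the median and 0.36 and 0.35 at 5 to 10 times. Above 10 times the median it was no higher, at 0.34 (0.31 to 0.36) and 0.31 (0.29 to 0.33). Because these ratios are scaled by autosomal totals, a higher share in dense windows forces values below 0 in sparse ones. The negative values therefore do not show a loss of the mark in sparse windows. Domains chosen on the plus strand and measured on the minus strand had a median of 0.27, with 687 higher and 48 lower.

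**Figure D2:**
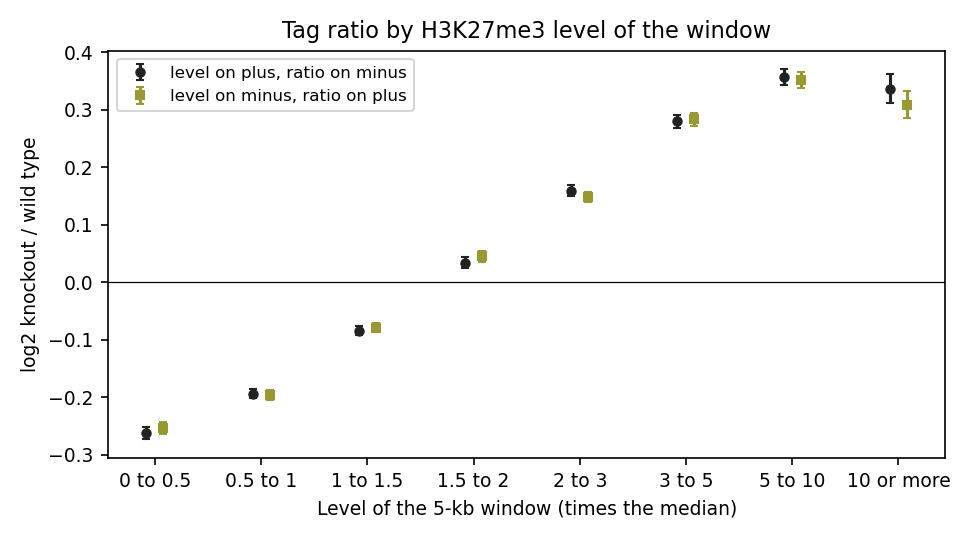
The log2 knockout over wild-type ratio (vertical axis) of 5-kb autosomal windows by their tag density in times the median (horizontal axis), with level and ratio taken from opposite strands and bars giving 95% counting intervals. The ratio goes from -0.26 and -0.25 in the emptiest windows to 0.36 and 0.35 at 5 to 10 times the median, and is 0.34 and 0.31 above that. Scaling by autosomal totals forces sparse windows below 0 when dense ones are above it.

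At developmental genes the mark was dense in both libraries, and all 10 regulators counted were marked, at 3 times the median or more. Pax2 among them had been seen as the widest domain before it was added, so its marking was known in advance. Olig2, a regulator of the oligodendrocyte lineage, had the highest level, 12.3 times the median in wild type and 16.7 in the knockout. Pax6, an eye regulator, stood at 9.29 and 12.2 times and Lhx2 at 9.12 and 12.1. Relative to all autosomal tags, 9 of the 10 were above 0, and the pooled log2 ratio was 0.43 (0.34 to 0.52), against 0.08 with domain scaling. Myod1, the muscle regulator, was the only one of the 10 that rose by the rule with autosomal scaling, and its call was lost with domain scaling. With background scaling Sox9, Gata4 and Pax2 passed as well. It held 60 wild-type and 66 knockout tags, which after scaling to the library totals gave a log2 ratio of 0.82 (0.30 to 1.35). Tag numbers given for loci and domains are before scaling. T (brachyury) was at -0.05 (-0.48 to 0.38), with 123 and 74 tags, an interval that includes the domain median. The 4 Hox clusters had log2 ratios of 0.43 (0.28 to 0.58) for Hoxa, 0.32 (0.19 to 0.44) for Hoxb, 0.24 (0.12 to 0.36) for Hoxc and 0.29 (0.17 to 0.42) for Hoxd, with none past 1.5-fold. Their pooled ratio of 0.31 (0.25 to 0.37) became -0.04 with domain scaling. Cdkn2a, the cell-cycle inhibitor locus and a classical Polycomb target, was at 6.72 and 8.96 times the median, with a ratio of 0.41 (0.13 to 0.70) that was 0.06 with domain scaling.

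Genes of other blood lineages carried intermediate levels. Gata3, a T-cell regulator, was at 5.19 and 6.04 times the median, and Pax5, the B-cell regulator, at 3.22 and 3.67. Of the 3 T and NK cell loci, Cd3e, part of the T-cell receptor complex, rose from 59 to 64 tags (log2 0.80, 0.27 to 1.34), a call lost with domain scaling, and Gata3 and Bcl11b did not pass the rule. The pooled ratio of these 3 was 0.41, and 0.06 with domain scaling. None of the 3 B-cell loci passed, and their pooled ratio of 0.18 (0.06 to 0.29) was -0.17 with domain scaling.

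Genes tied to macrophage identity and activation were mostly below the marking threshold of 3 times the median. Nos2, the inducible nitric oxide synthase, was marked at 4.04 and 4.32 times, with a ratio of 0.10 (-0.24 to 0.43). Klf4, a regulator of macrophage polarisation, was at 2.77 and 3.90 times the median. Of 6 macrophage identity loci, Cebpa and Cd14 rose and Itgam fell, and 3 did not pass. Cebpa, a myeloid transcription factor, went from 17 to 23 tags (log2 1.12, 0.15 to 2.12). Cd14, the lipopolysaccharide co-receptor, went from 8 to 14 (1.49, 0.14 to 2.95). Itgam, the integrin CD11b, fell from 65 to 22 tags (-0.88, -1.65 to -0.16). With domain scaling Cebpa and Cd14 no longer passed, and Itgam passed under all 3 scalings but not with all tags kept (-0.54). The pooled ratio of the 6 was 0.03 (-0.34 to 0.40), and -0.32 with domain scaling.

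Loci tied to alternative activation, the state that interleukin 4 induces, did not move together. Of 8, none rose, Mrc1 and Il4ra fell and 6 did not pass. Mrc1, the mannose receptor, had 103 and 41 tags (-0.64, -1.20 to -0.11). Il4ra, the interleukin 4 receptor, had 48 and 16 (-0.90, -1.81 to -0.06). Both calls were lost with background scaling. That of Mrc1 was also lost with all tags kept, and its ratio was -1.27 on the plus strand and -0.10 on the minus strand. Mrc1 was below the median density in both libraries, at 0.84 times in wild type and 0.54 in the knockout. Il4ra was below it only in the knockout library, at 1.17 and 0.63 times. Arg1, the arginase that marks this state, held only 10 tags in each library. The pooled ratio was -0.06 (-0.27 to 0.14), with 0.07 under background and -0.41 under domain scaling. This was at the 38.1 percentile of 10000 random sets matched on length and level.

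Interferon regulatory factors showed no call among 4 loci with any of the 3 scalings. Irf4 was at 2.68 times the median in wild type and 2.53 in the knockout, with 58 and 34 tags and a ratio of -0.08 (-0.74 to 0.55). That interval, with autosomal scaling, excludes a 2-fold difference either way, and smaller ones were not resolved. Irf8 was at 0.20 (-0.35 to 0.75), Irf5 at -0.27 and Irf1 at -0.64 (-2.29 to 0.81). Their pooled ratio of -0.03 (-0.39 to 0.32), 0.10 under background scaling and -0.39 under domain scaling, stood at the 23.2 percentile of matched random sets.

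Among 8 inflammatory loci, none rose, Il6 and Cxcl10 fell and 6 did not pass. Il6, a cytokine gene, had 22 wild-type and 5 knockout tags (-1.45, -3.21 to -0.01), a call lost with background scaling. Cxcl10, an interferon-induced chemokine gene, had 20 and 1 (-3.64, -9.01 to -0.99) and passed under all 3 scalings. Tnf held 8 and 1 tags and did not pass. The pooled ratio was -0.05 (-0.30 to 0.19), with 0.08 under background and -0.40 under domain scaling. It stood at the 6.18 percentile of matched random sets, whose median was 0.17. Of the 3 loci for H3K27 enzymes, Ezh2, the methyltransferase, fell from 73 to 20 tags (-1.18, -1.97 to -0.45) and passed under all 3 scalings, while Eed, at 21 and 12 tags, and Kdm6b did not pass with autosomal scaling. Those 3, the targeted gene among them, pooled to -0.95 (-1.53 to -0.40), where matched random sets had a median of -0.39. Ezh2 was unmarked, at 0.876 times the median in wild type and 0.386 in the knockout. None of the 7 housekeeping loci passed with autosomal scaling, Actb held 2 and 6 tags and Gapdh 3 and 5, and their pooled ratio was -0.13 (-0.71 to 0.43), with 0.0023 under background and -0.48 under domain scaling, where Eef1a1, a translation factor, passed as lower at -1.75 (-3.78 to -0.14). The percentiles of the 11 groups went from 1.99 for the H3K27 enzymes to 90.2 for the developmental regulators. Over all 57 loci with autosomal scaling, 4 were called higher and 6 lower, where counting error alone gave 0.661 and 0.704 on average. The 20 marked loci had 2 higher and 0 lower with that scaling, and the 37 unmarked loci 2 higher and 6 lower. This balance turned with the scaling, since over all 57 loci background scaling gave 7 higher and 3 lower, and domain scaling 0 and 8. With autosomal scaling, which forces sparse windows below 0 here, autosomal windows under 1.5 times the median had ratios from -0.26 to -0.08. All 6 lower calls with that scaling lay at mean levels below 1.5 times the median. Of these calls, none passed on both strands when each strand was taken alone, with fewer tags, though all kept their direction on both.

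**Figure D3:**
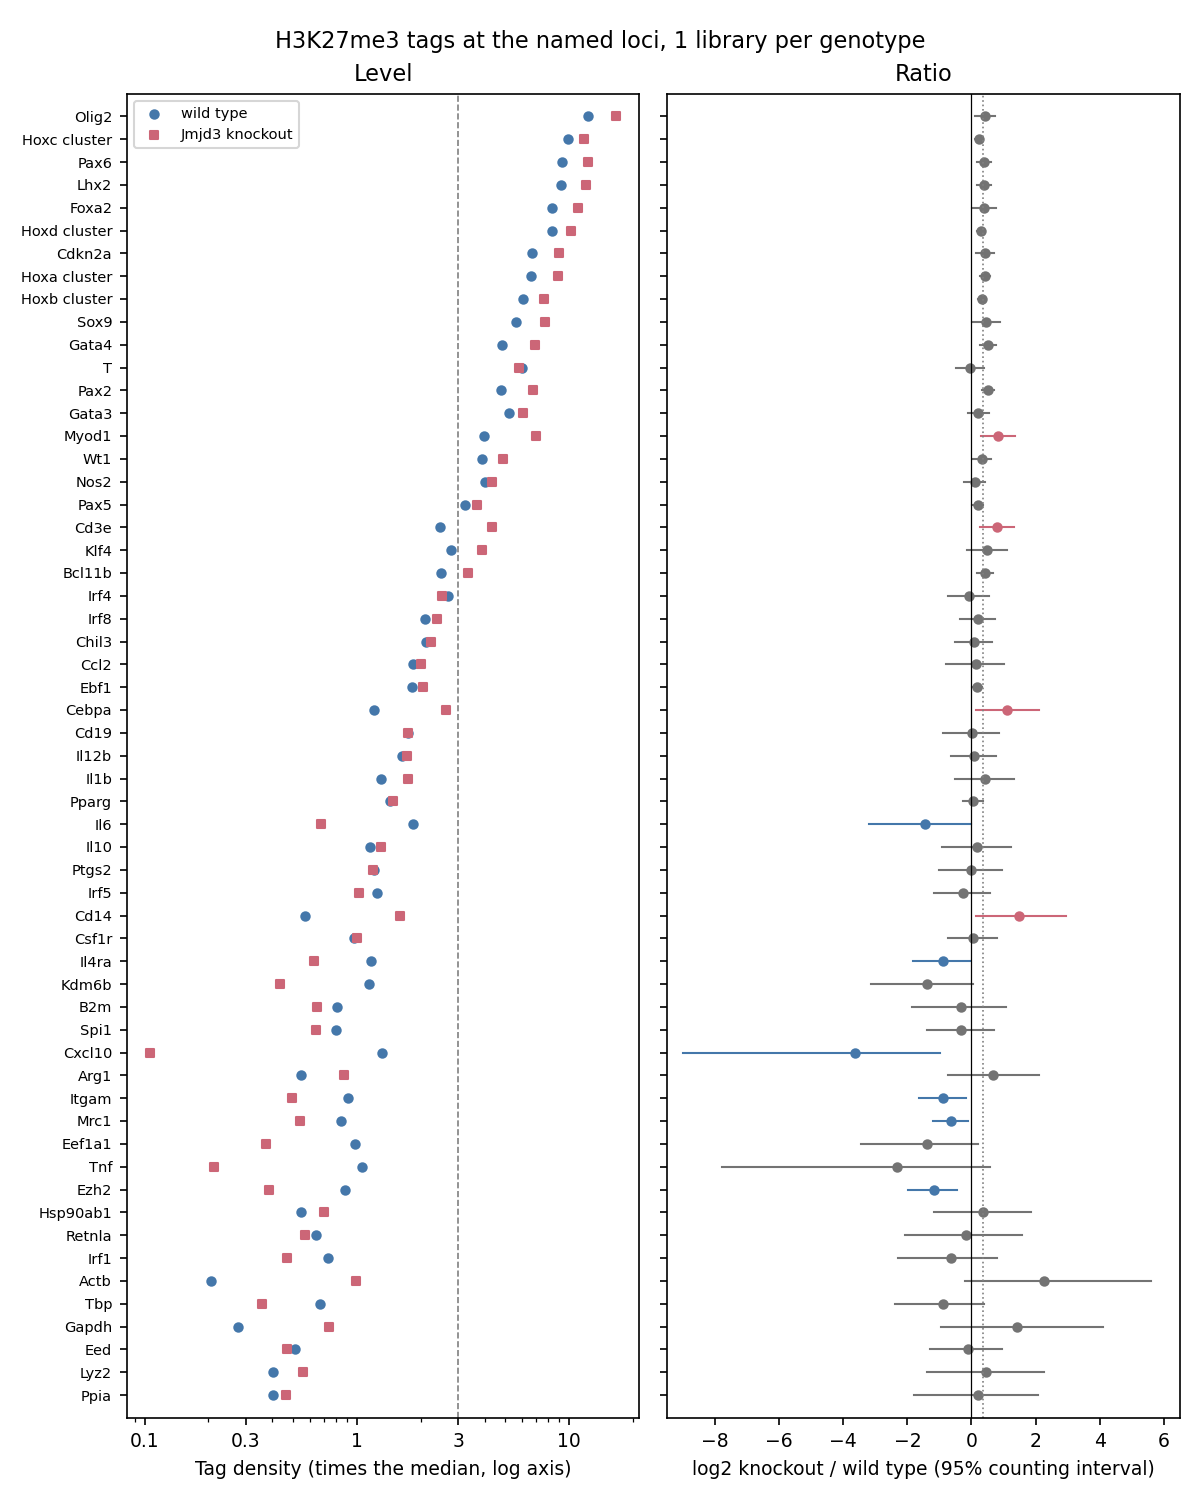
Tag density of the 57 named loci in times the median on a log axis (left) and their log2 knockout over wild-type ratio with 95% counting intervals (right), 1 library per genotype, with loci ordered by mean level. The dashed line is the marking threshold of 3, the dotted line the domain median of 0.35, and red and blue points on the right are the 4 loci called higher and the 6 called lower with autosomal scaling, of which all 4 higher calls are lost with domain scaling.

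The domains with the largest rises were mostly narrow and held few wild-type tags. The highest lower bound belonged to a 5-kb domain on chromosome 8 from 28175001 to 28180000, with 5 wild-type and 22 knockout tags (log2 2.82, 1.39 to 4.58). Of wider domains, 1 of 25 kb on chromosome 17 from 35555001 to 35580000 rose from 107 to 156 tags (1.23, 0.87 to 1.60), and 1 of 20 kb on chromosome 14 from 69945001 to 69965000 from 67 to 103 (1.31, 0.85 to 1.77). On chromosome 8 a domain of 25 kb from 19920001 to 19945000 went from 72 to 111 (1.31, 0.87 to 1.76). Another of the largest rises, from 19975001 to 19980000, lay near it, so these rises are not all separate regions. The 25-kb domains on chromosomes 8 and 17 were read fewer times per distinct position than the library means. The values were 1.86 and 2.35 in wild type and 2.53 and 2.58 in the knockout. Without an input library, these rises cannot be read as rises of the mark alone. The largest falls were smaller. A 5-kb domain on chromosome 5 from 140285001 to 140290000 fell from 28 to 5 tags (-1.80, -3.53 to -0.41), and a 15-kb domain on chromosome 3 from 25435001 to 25450000 from 86 to 32 (-0.74, -1.37 to -0.14). No gene was assigned to these domains, because no annotation of mm9 was used here.

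Some of the densest domains were stacks of repeated tags, while others were dense in distinct positions. The 10 kb of chromosome 2 from 98500001 to 98510000 held 3.06% of all wild-type and 3.05% of all knockout tags, read 136 and 132 times per distinct position. On chromosome 9 from 2995001 to 3040000, 0.591% and 0.589% of the tags lay in 45 kb. By contrast, the 15 kb of chromosome 17 from 39975001 to 39990000 was read 2.32 and 2.49 times per distinct position, below the library means. It stood at 129 times the median in wild type and 146 in the knockout. Without an input library, such a density cannot be read as the level of the mark. The stacked places on chromosomes 2 and 9 took nearly equal shares of both libraries, and leaving out all windows with stacked tags kept the domain median at 0.35.

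Autosomes differed little between the libraries. Chromosome 11 had the highest density, 1.22 times the autosomal median in wild type and 1.28 times in the knockout. The highest log2 ratio of an autosome was 0.08 (0.07 to 0.09) on chromosome 9 and the lowest -0.07 (-0.08 to -0.06) on chromosome 3.

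A stretch of chromosome 11, noticed only after its counts were seen, held almost no knockout tags. From 71021945 to 71109880, 87.9 kb, there were 90 wild-type and 2 knockout tags, where 55.9 knockout tags would match the wild-type density. The log2 ratio was -4.81 (-7.87 to -2.91), or 3.58% of wild type, with edges set by the missing knockout tags themselves. A fixed window of 100 kb over it, from 71010001, held 100 and 5 tags (-3.64, -5.29 to -2.37). The stretch began 1.79 Mb from Kdm6b. In the surrounding 70800001 to 71400000 without it, 781 wild-type and 399 knockout tags gave -0.28 (-0.46 to -0.11). The sides differed, with 0.20 (-0.08 to 0.49) to the left and -0.57 (-0.80 to -0.34) to the right. The left value includes 60 kb from 70900001 that held 44 wild-type and 77 knockout tags (1.49, 0.94 to 2.06). Those 60 kb were picked from these same counts. Among 235160 overlapping windows of 100 kb, the region with the next lowest upper bound, on chromosome 4, had 90 and 16 tags (-1.81, -2.67 to -1.03).

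**Figure D4:**
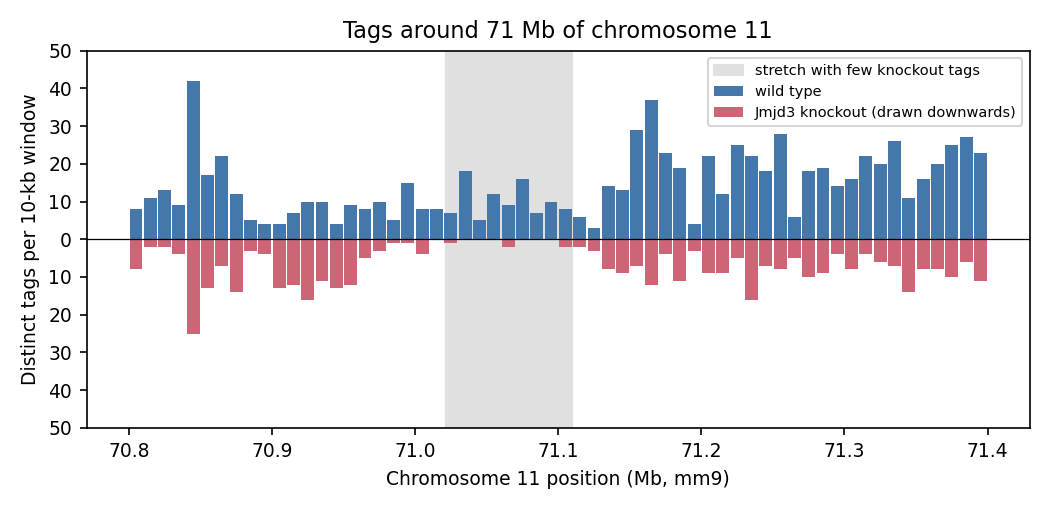
Distinct tags in 10-kb windows (vertical axis, number of tags) along chromosome 11 (horizontal axis, Mb of mm9), with wild type drawn upwards and the knockout downwards, 1 library each. The grey stretch holds 90 wild-type and 2 knockout tags, while both libraries have tags on either side.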

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

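Distinct tags were also present on chromosomes outside the autosomal comparison, above the 3 tags that a count of 0 allows. Chromosome X held 76716 in the wild-type library and 44085 in the knockout library. Chromosome Y held 3610 and 1654, and the mitochondrial genome 34 and 18. Per Mb and relative to each library's autosomal tags, chromosome X stood at 0.356 and 0.331 of the autosomal median and chromosome Y at 0.176 and 0.130. The log2 knockout over wild-type ratio was -0.11 (-0.13 to -0.10) on X and -0.44 (-0.52 to -0.36) on Y.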

How the results depend on the processing

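The direction of the domain median held under every alternative except domain scaling, which sets it to 0 by construction. The locus ratios at Kdm6b stayed negative throughout, from -2.22 on the minus strand to -0.32 on the plus strand. Across the other 56 loci, 347 of 374 alternative values stayed within the counting interval, 27 moved out of it and 0 called loci changed sign, and 6 values at 5 loci had no ratio because a library held 0 tags. In the following, "median" is the median log2 ratio of domains and "share ratio" the ratio of the libraries' shares of tags in domains. With all tags, 3356 domains were higher and 384 lower, the share ratio was 1.21 and the Hox clusters pooled to 0.21. On the plus strand, 33 were lower and the share ratio was 1.29. On the minus strand the median was 0.37, 27 were lower and the share ratio was 1.30. Background scaling gave a median of 0.48, 2003 higher, 3 lower and a Hox value of 0.44. Domain scaling gave 0, 161 higher, 161 lower and a Hox value of -0.040. At 2 times the median there were 20370 domains over 378.7 Mb, with a median of 0.27, 83 lower and a share ratio of 1.21. At 5 times there were 3879 over 37.3 Mb, with 0.37, 605 higher, 3 lower and 1.29. Windows of 2 kb gave 26582 domains, a median of 0.42, 2313 higher, 47 lower and a share ratio of 1.30. Windows of 10 kb gave 5312, 0.32, 642, 9 and 1.255 in the same order. With the wild-type library thinned, the median was 0.27, 33 were lower and the share ratio was 1.24. Domains called in wild type alone had a median of 0.082, 376 higher, 187 lower and a share ratio of 1.14. Those called in the knockout alone numbered 18837 over 279.1 Mb, with 0.57, 3328 higher, 2 lower and 1.36. A 2-fold rule left 472 higher and 7 lower, by construction. Alternatives chosen after seeing the data follow. Domains chosen on plus and measured on minus had a median of 0.27, 687 higher, 48 lower and a share ratio of 1.24. The reverse gave 0.27, 687, 56 and 1.24. Domains of at least 20 kb had 0.34, 214 higher and 1 lower, out of fewer domains. Apart from the construction named above, the cause was not tested. The promoter and gene-list alternatives were not run, since no annotation of mm9 was used. No paired analysis was possible because each genotype has 1 library.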

Other observations

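The count with all tags kept, the domains called in each library alone and the random splits of domains were planned before the data were examined, and the other tests in this part, with the bounds set for all of them, were chosen after the results had been seen.

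The higher ratio of marked domains in the knockout library is a pattern in 1 library per genotype. Counting of repeated tags as the whole source is argued against by medians of 0.35 with 1 tag per position and 0.36 with all tags kept. Neither count tests the lower share of distinct positions in the knockout library. With all tags kept the share ratio fell from 1.27 to 1.21. Choosing domains on noisy windows as the whole source is argued against by the median of 0.27 when domains are chosen on 1 strand and measured on the other, where random splits reached at most 0.07, although the choice moved the median from 0.082 for domains called in wild type alone to 0.57 for the knockout alone. A stronger pull-down over background in the knockout library may account for the pattern, since domains of at least 20 kb shared nearly the same shift, with an SD of 0.10 beyond counting error around a median of 0.34. Loss of Jmjd3 cannot be told apart from it with 1 library per genotype and no spike-in used here, and a difference in GC content between the libraries was not tested.

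The stretch without knockout tags at Kdm6b could be the targeted deletion. For a gene named in advance, counting error as the whole source is argued against only weakly, since 1.18% of random deals gave as full a stretch over the locus. That test replaced a count over all autosomes after the count was seen. By that count such stretches are common, with 2203 as full, against 1417 on average in 20 random splits. The evidence is thin, because the interval of the whole locus includes 0 and 3.34% of autosomal segments with its length and level lay on such a stretch. The deletion itself was not tested. An input library, or tags from a deeper library over the locus, would separate these.

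The near absence of knockout tags over 87.9 kb of chromosome 11, at 71021945 to 71109880, is harder to place. Counting error is argued against, since the fullest stretch without a knockout tag held 43 wild-type tags, against at most 36 in 20 random splits. A library-wide bias is argued against by the 100-kb scan, where this region had an upper bound of -2.37 and the next region one of -1.03. A structural or strain difference between 129 and B6 DNA, carried along with the targeted gene 1.79 Mb away, is a candidate explanation as a hypothesis. It stays open, because of the 8 next largest stretches without knockout tags 1 lay within 15 Mb of Kdm6b, at 82743208 to 82747147 with 34 wild-type tags, which decides neither way. An effect of Jmjd3 loss on the mark here was not tested.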
